A study of Mus musculus with 4 samples.

How the data were processed

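Single-cell RNA was measured in 4 libraries of CD11b+/CD45+ myeloid cells, each sorted by flow cytometry from the left brain hemisphere after a Percoll gradient. All mice were labelled as female and 4 months old and carried APP/PS1, the transgenes of an amyloid model of Alzheimer's disease. Of these, 2 libraries were labelled miR-155 cKO, with the microRNA miR-155 meant to be deleted in microglia, and 2 were Control. The labels call them biological replicates. Loss of miR-155 itself was not measured. The labels state neither which part of the miR-155 locus was deleted nor which Cre driver was used. Libraries were made with 10x Genomics 3′ v3.1 chemistry. In the deposited names cKO replicate 2 carries another run code than the other 3 libraries, so each group has at least 1 library of the shared code and only the cKO group has one of the other.

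The deposited matrices hold raw UMI counts per gene and barcode, which the authors made with Cell Ranger 4.0.0 on mm10 (per the labels and file headers). They were unfiltered and still held empty droplets. The counts were whole numbers with no normalization, over 32372 gene features. Of these, 128 identifiers were missing from the GENCODE M21 annotation (GRCm38) that gave gene positions and 3′ UTRs. The deposited barcodes (other: names, no measurement) and feature names per the file headers only label the matrix.

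The gene lists, state genes, cell type markers, thresholds, tests, the rule for named genes and most alternatives were chosen before the data were examined. Cells were barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Scrublet (in scanpy 1.11.5, expected doublet rate 0.04) scored each library, and the highest scores were removed at 0.8% per 1000 cells, 401 barcodes in all. Scrublet's own threshold called 2, 0, 0 and 0 doublets in cKO replicate 1, Control replicate 1, Control replicate 2 and cKO replicate 2, so the removal rests on the fixed rate. The 13539 cells left were log-normalised and clustered together (2000 variable genes, 30 principal components, 15 nearest neighbours, leidenalg 0.10.2 at resolution 1). Clusters were named from fixed marker genes of microglia, of border-associated macrophages (BAM), monocytes, other blood cells and of other brain cells. A cluster stayed unnamed when the markers among its leading genes did not point to 1 type, or when its depth was low and no marker was among those genes. Otherwise a cluster was named microglia-like when several microglia markers were detected and no other type had more markers among its leading genes.

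Genotype was tested in microglia-like cells on raw UMIs summed per library, 1 sum for each of the 4 libraries, since cells are not replicates. The fit used edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood F test, two-sided) with Benjamini-Hochberg adjustment at 0.05. CPM values are scaled with TMM factors. With 2 libraries per group the fit has 2 residual degrees of freedom, and its dispersions borrow strength across genes. The 17 gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), beside it with a correlation estimated from the residuals, and with fry. Counts of list members are also given adjusted over the list alone. For the genotype comparison the rule named the genes past the threshold with the same order in every cKO against every Control library and an average log2 CPM of at least 4, then the smallest p up to 10 per direction. It added up to 3 members of each list by p (some genes are not analysed here), and Mir155hg, Xist, P2ry12, Tmem119, Clec7a and Apoe as checks. Other fits named the 5 largest changes per direction by the same criteria, and predicted, ribosomal and mitochondrial genes were counted but not put forward outside their own lists.

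Seed sites of miR-155-5p were sought in the longest annotated 3′ UTR of each tested gene as AGCATTA, the match to nucleotides 2 to 8, with the longer AGCATTAA as an alternative. The median log2 fold change of genes with a site minus that of genes without one was set against 419 other heptamers of the same base composition, which gave an exact two-sided p by enumeration. Microglial states were called after thinning each cell to 2000 UMIs. A cell was MGnD-high (MGnD, the neurodegenerative or disease-associated microglial phenotype) with at least 3 of 12 fixed genes detected, and interferon-high or cycling with at least 3 of 12 others. MHC-II-high needed 2 of 4 genes. For each state a background was calculated for 2000 UMIs with the profile of the library's barcodes of at most 100 UMIs (free RNA). Shares were compared by exact two-sided permutation tests, whose smallest possible p with 2 libraries against 2 is 0.333, so no share could pass 0.05. MGnD-high cells were compared with the other microglia-like cells by edgeR on 2 sums per library with the library as a block, and a genotype by state interaction was tested in the same way. Differences of expression in the other cell classes were not tested, because none had at least 30 cells in every library.

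On simulated counts with the same 2 against 2 layout, 13214 genes were tested and 50 genes were planted at each fold. Planted genes had a mean above 100 counts per library, and all genes were drawn independently. The fit recovered 16.0% of planted genes at 1.25-fold, 80.0% at 1.5-fold, 96.0% at 2-fold and 100% at 4-fold. Recovery at lower counts was not simulated. False calls made up 12.6% of all calls, which is above the nominal 5%, and data without planted changes gave 1 call. The seed-site test gave an exact p = 0.00238 for a planted log2 shift of 0.1, the smallest it can give, and p = 0.493 without one. Fold changes were drawn independently for it from a normal distribution. No smaller shift was planted, so whether the test finds smaller shifts is not known. Alternatives covered DESeq2 1.42.0 and its size factors, no low-count filter, a replicate block, leaving out each library, other cell and doublet limits, thinning, cells and genes that could carry foreign RNA, and cells of single states. When a library was left out, the lone sample of its group was assumed to vary like the other group. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.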

Results

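The data are 4 libraries of sorted brain myeloid cells from APP/PS1 mice, 2 labelled miR-155 cKO and 2 Control. The deposited counts came to 41214799 UMIs in cKO replicate 1, 47574406 in Control replicate 1, 33889598 in Control replicate 2 and 33130800 in cKO replicate 2. After filtering, the same libraries held 3711, 4200, 2841 and 2787 cells, with median depths of 6097, 6046, 6346 and 7195 UMIs per cell. Barcodes of at most 100 UMIs, which hold mostly free RNA, took 14.9%, 11.2%, 16.3% and 17.8% of all UMIs in that order.

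Nearly all cells lay in clusters named microglia-like, with microglia markers such as P2ry12 and Tmem119 detected. A cluster resembling border-associated macrophages and a cluster led by Ttr also had 16 microglia markers detected, so detection alone does not set the class. The microglia-like share of cells was 91.3% ± 1.36 (SD, n = 2) in cKO and 89.2% ± 0.892 (SD, n = 2) in Control, with an exact permutation p = 0.333. Cells resembling border-associated macrophages, led by the MHC class II genes H2-Eb1, H2-Aa, H2-Ab1 and Cd74 and then Pf4, Mrc1 and Ms4a7, made up 0.561% ± 0.222 in cKO and 0.394% ± 0.389 in Control (SD, n = 2 each, exact p = 0.667). Monocyte-like cells, led by S100a8, Plac8, Chil3 and Ly6c2, made up 0.301% ± 0.222 in cKO and 0.386% ± 0.296 in Control (SD, n = 2 each, exact p = 0.667). The remaining 7.86% ± 1.36 of cKO and 9.99% ± 0.80 of Control cells (SD, n = 2 each, exact p = 0.333) lay in unnamed clusters, mostly of low depth. No cluster was named as neutrophils, lymphocytes, dendritic cells, mast cells, neurons, vascular, glial, choroid plexus or erythroid cells. These tests compared all cells, and with at least 2000 UMIs per cell the microglia-like difference was -0.180 points and that of unnamed cells 0.255 points, the opposite direction in both. The BAM-like difference of 0.167 points was -0.108 without Control replicate 1, 0.442 without Control replicate 2, 0.324 without cKO replicate 1 and 0.0103 without cKO replicate 2, and the monocyte-like difference of -0.0848 points ranged from -0.294 to 0.125.

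The first question was whether the targeted gene could be seen. Mir155hg, the host transcript of miR-155 (chromosome 16, 84703167 to 84715245, plus strand, GRCm38), gave 1 UMI in each cKO library, 7 UMIs in Control replicate 1 and 10 in Control replicate 2, over all microglia-like cells. The ratio of cKO to Control levels was 0.125, with a 95% exact counting interval of 0.0140 to 0.528 from 2 against 17 UMIs. The Mir155 hairpin lies at 84714140 to 84714204 in exon 2 of Mir155hg, the last exon. Because the deleted part is not stated, these counts only give the level of the host transcript, and they cover counting error alone. Xist, expected in female cells, was at 1852 and 1700 CPM in the cKO libraries and 1813 CPM in Control replicate 2, but at 0.405 CPM in Control replicate 1.

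The next question was how microglial states were distributed. MGnD-high cells had UMIs of genes such as Clec7a, Itgax, Lpl, Cst7 and Spp1. They made up 23.3% and 13.9% of microglia-like cells in cKO replicates 1 and 2, and 28.4% and 28.0% in Control replicates 1 and 2. The means were 18.6% ± 6.68 in cKO and 28.2% ± 0.272 in Control (SD, n = 2 each), a difference of -9.62 points with exact permutation p = 0.333, the smallest possible. Both cKO libraries lay below both Control libraries, but the cKO libraries differed from each other by nearly as much. Within the 3 libraries of the shared run code the difference was -4.90 points, which is the value without cKO replicate 2; the other code holds 1 library. Heat-shock transcripts went the other way, being detected in a larger part of the cells in both cKO libraries. Cells without a UMI of Hspa1a, Hspa1b or Dnajb1 made up 56.6% and 39.8% of cells in cKO replicates 1 and 2. In Control replicates 1 and 2 they made up 63.7% and 70.5%. Droplets of free RNA alone at the thinned depth would give 35.3% and 12.4% MGnD-high in cKO replicates 1 and 2. In Control replicates 1 and 2 they would give 51.4% and 56.2%. These values lay above the observed MGnD-high shares except in cKO replicate 2, and were also lower in cKO. At its share of each library's UMIs free RNA would give 0.152% to 1.44%, but how much of it a cell holds was not measured.

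Droplets of microglia-like cells with UMIs of at least 2 of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 (MHC-II-high) were more frequent in both cKO libraries, at 3.73% in each, than in Control replicates 1 and 2, at 1.93% and 2.57%. The Control mean was 2.25% ± 0.454 (SD, n = 2), and the difference of 1.47 points had an exact permutation p = 0.333. It was 0.617 points with 1 gene more asked for, 0.868 points with cells thinned to 1000 UMIs and 1.67 points without cells carrying markers of another class. As a background, droplets of free RNA alone at the same depth would give 3.12% and 2.66% in cKO replicates 1 and 2 and 2.04% and 5.56% in Control replicates 1 and 2. With free RNA at its share of each library's UMIs they would give 0.0290% to 0.183%, but how much of it a cell holds was not measured. Interferon-high cells, with genes such as Ifit3, Isg15 and Irf7, made up 14.0% ± 0.817 in cKO and 14.97% ± 1.56 in Control (SD, n = 2 each, exact p = 0.667). Their difference of -0.965 points was -3.06 with 1 gene fewer asked for, where both cKO libraries lay below both Control libraries (exact p = 0.333), and 0.600 with 1 gene more. It was 0.141 points without Control replicate 2, -2.07 without Control replicate 1, -0.387 without cKO replicate 1 and -1.54 without cKO replicate 2. Free RNA alone would give 10.9% and 9.33% interferon-high droplets in cKO replicates 1 and 2, and 11.9% and 14.7% in Control replicates 1 and 2. At its share of each library's UMIs it would give 0.0384% to 0.152%. Cycling cells, with Mki67 and Top2a, made up 0.986% ± 0.488 in cKO and 1.253% ± 0.238 in Control (SD, n = 2 each, exact p = 0.667). Their difference was 0.0777 points without cKO replicate 2 and 0.134 points with cells thinned to 1000 UMIs.

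**Figure D1:**
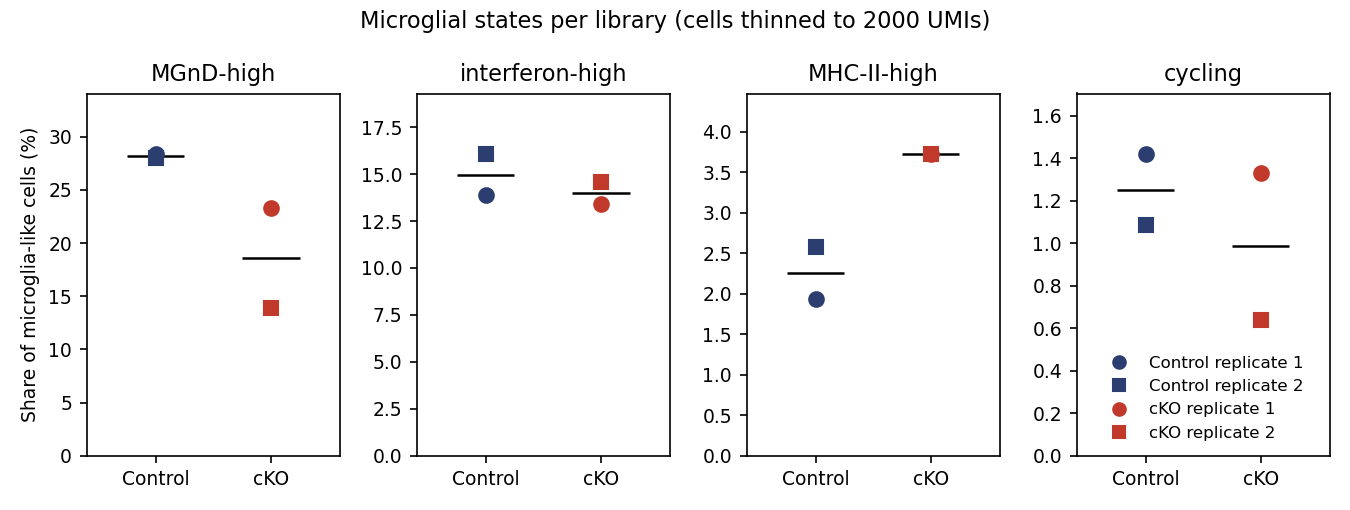
Share of microglia-like cells (%) in each of 4 states, per library, with cells thinned to 2000 UMIs; circles are replicate 1, squares replicate 2, and lines are group means. The MGnD-high share was 23.3% and 13.9% in the cKO libraries and 28.4% and 28.0% in the Control libraries.

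In microglia-like cells, 4 of 13361 tested genes changed with genotype, 3 higher and 1 lower in cKO, each in the same order in 4 of 4 libraries. Cdkn1a, an inhibitor of cyclin-dependent kinases (chromosome 17, 29090976 to 29100727), rose from 32.2 ± 4.80 to 66.4 ± 4.70 CPM, a log2 fold change of 1.04 (SE 0.11). Iigp1, an interferon-inducible GTPase that acts against intracellular pathogens (chromosome 18, 60376027 to 60392634), rose from 6.69 ± 0.875 to 16.5 ± 1.91 CPM, 1.28 (SE 0.14) on the log2 scale. Esr1, the estrogen receptor alpha (chromosome 10, 4611593 to 5005614), was counted at 5.17 ± 0.895 CPM in Control and 13.2 ± 0.433 CPM in cKO, 1.37 (SE 0.15). The labels name no Cre driver. Receptor sequence from a Cre allele, if counted as Esr1, cannot be told apart from a rise of the gene itself. Hist1h2ac, a histone H2A gene (chromosome 13, 23681467 to 23683948), fell from 72.5 ± 10.3 to 38.5 ± 1.92 CPM, -0.91 (SE 0.10). Errors of CPM are SD with n = 2 per group, and each of the 4 genes had an edgeR adjusted p = 0.0299. Iigp1 and Esr1 came in by their small p, since their average log2 CPM was under 4.

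At an unadjusted p under 0.05 there were 1039 genes, where chance gives 668. This count was 642 with DESeq2, 564 with MGnD-high cells left out, 574 without cKO replicate 2 and 2407 without cKO replicate 1, so the excess was not seen in every setting. In the edgeR fit of all 4 libraries, 39.7% of tested genes had groups that did not overlap, where chance gives 33.3%. In log2 CPM of the tested genes, cKO replicate 1 correlated with Control replicates 1 and 2 at 0.9923 and 0.9934 (Pearson). The correlation was 0.9918 between the cKO libraries and 0.9914 between the Control libraries, so whole profiles were not closest within groups. The 4 genes stayed past the threshold when any single library was left out, but the count of genes did not stay near 4. It was 331 without cKO replicate 1, 84 without Control replicate 1, 107 without Control replicate 2 and 8 (5 higher, 3 lower) without cKO replicate 2, which leaves the 3 libraries of the shared run code; the lone sample of a group was assumed to vary like the other group. With the replicate numbers as a block, 6 genes passed, 5 higher and 1 lower, including the 4. DESeq2 called 25 genes (7 higher, 18 lower). With interferon-high cells left out, an alternative added after the result was seen, edgeR called 0 genes, with 908 genes at an unadjusted p under 0.05. Iigp1 was then at a log2 change of 0.59, while Cdkn1a (0.98), Esr1 (1.38) and Hist1h2ac (-0.93) had adjusted p values of 0.0619, 0.0619 and 0.0672. Leaving out cells with UMIs of at least 2 markers of another class kept 2259 of 3423 microglia-like cells in cKO replicate 1 and 1577 of 2517 in cKO replicate 2. It kept 2439 of 3774 in Control replicate 1 and 1646 of 2517 in Control replicate 2. This ended the calls of Cdkn1a (log2 0.90, adjusted p = 0.223) and Iigp1 (1.28, adjusted p = 0.0696). MGnD-high cells left out ended those of Esr1 (1.28, adjusted p = 0.0518) and Hist1h2ac (-1.02, adjusted p = 0.0652), and thinned cells that of Iigp1 (1.06, adjusted p = 0.0515). Over the 17 settings, Cdkn1a, Esr1 and Hist1h2ac passed in 15 each and Iigp1 in 14, with largest adjusted p values of 0.223, 0.0619, 0.0672 and 0.807 in that order.

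The other named genes did not pass the adjustment. Higher values in cKO were seen for the guanylate-binding protein gene Gbp2 (log2 0.87), the chemokine Cxcl10 (1.94, 60.5 ± 20.4 against 16.2 ± 9.07 CPM, SD, n = 2 each) and the inducible heat-shock genes Hspa1a (1.51) and Hspa1b (1.46). Crtap (0.70), Grap (0.42) and the potassium channel gene Kcnj12 (1.247) also had higher values. Lower values were seen for the lipoprotein lipase gene Lpl (-0.82, 129 ± 24.2 against 229 ± 15.2 CPM, SD, n = 2 each), Mamdc2 (-1.72), Crip1 (-0.83), Il4i1 (-0.72), the lysosomal beta-galactosidase gene Glb1 (-0.54), the oxidase subunit gene Cybb (-0.68), Fgf13 (-0.62) and Myo1e (-0.64). The fractalkine receptor gene Cx3cr1 (chromosome 9, 119901616 to 120069879) was at 2411 ± 189 CPM in cKO and 4221 ± 494 CPM in Control (log2 -0.81, SD, n = 2 each, edgeR adjusted p = 0.323). Crtap and Glb1 lie on the same chromosome, from 114375134 and from 114401076. The labels do not state which Cre driver the cKO mice carried, so the sequence around Cx3cr1, and any receptor sequence counted as Esr1, is not known. Adjusted p values of all these genes ran from 0.0811 for Crtap to 0.367 for Myo1e. Among the check genes, P2ry12 had a log2 change of 0.09, Tmem119 0.28, Clec7a -0.71 and Apoe -0.43, and none passed.

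**Figure D2:**
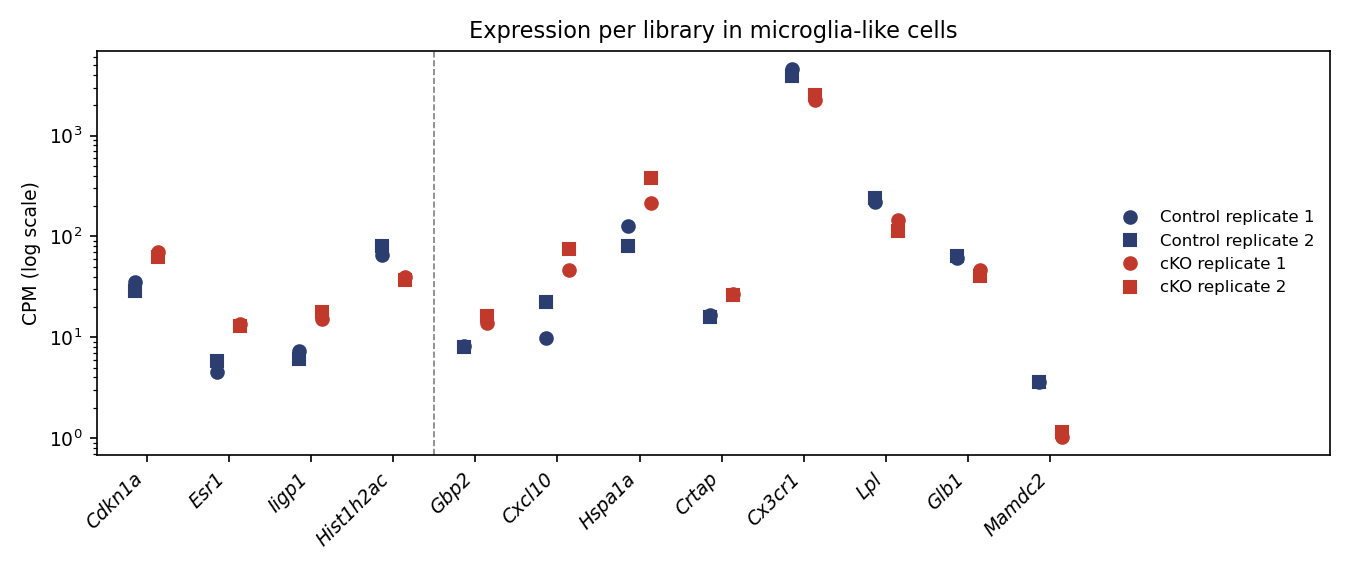
CPM per library (log scale) of 12 named genes in microglia-like cells; red is cKO, blue is Control, circles are replicate 1 and squares replicate 2. The 4 genes left of the dashed line passed the adjusted threshold, and the others did not.

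The MGnD or disease-associated list had lower values in cKO in 39 of its 42 members, with a median log2 change of -0.48. None passed over all genes, while 26 lower and 1 higher passed when adjusted over the list alone; Lpl, Mamdc2 and Cybb had the smallest p. Camera called the list lower (adjusted p = 1.67e-34), and with an estimated correlation the adjusted p = 0.320. The median was -0.24 without cKO replicate 2, -0.75 without cKO replicate 1 and -0.10 with MGnD-high cells left out. Beside this, heat-shock transcripts Hspa1a and Hspa1b were at 215 and 174 CPM in cKO replicate 1, 378 and 296 CPM in cKO replicate 2, 127 and 102 CPM in Control replicate 1, and 81.1 and 68.3 CPM in Control replicate 2.

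Lists of lipid, lysosome and energy genes also had lower values in cKO. Of 32 cholesterol and lipid genes 26 were lower (median -0.25), 9 of them adjusted over the list alone; Idi1, of sterol synthesis, was at -0.75. Of 33 lysosome and phagocytosis genes 23 were lower (median -0.13), 2 of them, Glb1 (-0.54) and Axl (-0.54), adjusted over the list alone, and Cd68, which did not pass, was at -0.29. Camera called both (adjusted p = 4.18e-12 and 3.98e-05), and with an estimated correlation the adjusted p = 0.320 for each. Glb1 lies within 10 Mb of Cx3cr1, as does Ccrl2 of the NF-kB list below. Strain variants carried beside that locus could not be told apart for these genes. Glycolysis genes were lower in 13 of 17 (median -0.09), among them Pkm at -0.34, Gapdh at -0.40 and Pgk1 at -0.28, with camera adjusted p = 6.81e-04 and adjusted p = 0.453 with an estimated correlation. Nuclear genes of oxidative phosphorylation were lower in 35 of 36 (median -0.19), with Ndufa1 at -0.26, Uqcr11 at -0.30 and Ndufa2 at -0.27. All 13 mitochondrially encoded genes were lower (median -0.36), with mt-Nd4l at -0.34, mt-Nd6 at -0.37 and mt-Nd5 at -0.33, as were all 62 cytosolic ribosomal protein genes (median -0.29), with Rpl35 and Rpl41 at -0.42. Camera called these 3 lists (adjusted p = 6.62e-12, 2.59e-09 and 4.39e-24), and with an estimated correlation the adjusted p = 0.320 for each; no member passed when adjusted over the list alone. With MGnD-high cells left out the medians of the lipid, lysosome and glycolysis lists were -0.00, -0.00 and -0.01, those of the oxidative phosphorylation, mitochondrial and ribosomal lists -0.06, -0.24 and -0.13. The lipid, lysosome and glycolysis calls ended there (camera adjusted p = 0.295, 0.298 and 0.691), while the oxidative phosphorylation, mitochondrial and ribosomal calls held. In cells thinned to 2000 UMIs the lipid and lysosome medians were -0.10 and -0.07. Without cKO replicate 2 the lipid, lysosome, glycolysis and ribosomal medians were -0.14, -0.08, -0.05 and -0.19. The glycolysis call ended without cKO replicate 2 or Control replicate 2 (camera adjusted p = 0.112 and 0.0612). Without Control replicate 2 the lipid, oxidative phosphorylation and mitochondrial medians were -0.14, -0.11 and -0.13. Without cKO replicate 1 the lipid and glycolysis medians were -0.39 and -0.21, and without Control replicate 1 the mitochondrial and glycolysis medians were -0.56 and -0.15.

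Genes of the interferon-gamma pathway had higher values in cKO in 38 of 42 members (median 0.25). Over all genes Iigp1 passed, and 14 higher and 1 lower passed when adjusted over the list alone. Camera called the list (adjusted p = 1.25e-17), with adjusted p = 0.320 with an estimated correlation. Its median was 0.16 with cells carrying markers of another class left out. The type I interferon list was mixed, with 29 of 44 higher and a median of 0.08; Ifit1 (0.59) and Mx1 (0.36) had higher values and Ifi27l2a (-0.61) lower. Camera called it at an adjusted p = 0.0252, with 0.463 as the adjusted p with an estimated correlation; 1 higher and 1 lower passed when adjusted over the list alone. Its median was -0.16 with interferon-high cells left out, -0.01 without cKO replicate 2 and -0.00 without Control replicate 1. It was 0.02 with cells carrying markers of another class left out (camera adjusted p = 0.738), 0.13 in thinned cells and 0.15 with MGnD-high cells left out, and the call was lost with no doublets removed (camera adjusted p = 0.0627).

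MHC class I genes were higher in 15 of 19 (median 0.11), with camera adjusted p = 7.71e-04 and adjusted p = 0.320 with an estimated correlation. The members with the smallest p were H2-Q6 (log2 0.66), H2-Q7 (0.47) and H2-Q4 (0.33). MHC class II genes were higher in 10 of 14 (median 0.16), with camera adjusted p = 0.00239 and adjusted p = 0.463 with an estimated correlation. By smallest p its first members were H2-Aa (log2 0.75), H2-Eb1 (0.80) and Ifi30 (0.18). The class II median was -0.02 without Control replicate 1 and 0.13 without cKO replicate 1, and the call was lost in both. It was also lost with cells carrying markers of another class left out (median 0.13, camera adjusted p = 0.0727). NF-kB and cytokine genes were higher in 21 of 27 (median 0.16), among them Ccl7 (0.93), Tnfaip3 (0.30) and Ccrl2 (0.43), with camera adjusted p = 6.26e-06 and adjusted p = 0.320 with an estimated correlation. All 32 immediate-early and dissociation stress genes had higher values (median 0.27), with Klf6 at 0.45, and 2 passed when adjusted over the list alone, with camera adjusted p = 2.41e-13 and adjusted p = 0.320 with an estimated correlation. No member of the MHC or NF-kB lists passed when adjusted over the list alone. Without cKO replicate 2 the stress and MHC class I medians were 0.12 and 0.07, and the NF-kB median was 0.29 without Control replicate 2 and 0.10 without Control replicate 1. Without Control replicate 1 the camera calls of the MHC class I and NF-kB lists were lost (adjusted p = 0.135 and 0.319).

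Homeostatic microglia genes were higher in 26 of 35 (median 0.06), with Upk1b at 0.45 and Serpinf1 at 0.27, whereas Cx3cr1 was the 1 member that passed, lower, when adjusted over the list alone. Camera called the list at an adjusted p = 0.0224, with adjusted p = 0.463 with an estimated correlation. Its median was 0.14 without Control replicate 1, 0.09 without cKO replicate 1, 0.03 without cKO replicate 2, 0.04 without Control replicate 2 and 0.00 with MGnD-high cells left out, and in thinned cells it was 0.03; the call held without Control replicate 1 but in none of these other settings. Cell cycle genes were lower in 26 of 30 (median -0.17), with Hist1h2ap at -0.77, Stmn1 at -0.44 and Birc5 at -0.56, and camera adjusted p = 5.17e-05 against adjusted p = 0.453 with an estimated correlation. Their median was 0.23 with MGnD-high cells left out, and -0.00 without cKO replicate 2, -0.49 without cKO replicate 1, -0.11 without Control replicate 2 and -0.26 without Control replicate 1. In thinned cells it was -0.04 with the camera call lost (adjusted p = 0.0727), and with cells carrying markers of another class left out it was -0.42. TGF-beta genes, among them Itgb8 (-1.03), Tgif2 (0.22) and Smad4 (0.15), were not called (camera adjusted p = 0.416), and their median of 0.04 and mean of -0.00 differ in sign. Itgb8 was near the floor, at 0.356 and 0.239 CPM in cKO replicates 1 and 2 and 0.780 and 0.408 CPM in Control replicates 1 and 2. No member of the cell cycle or TGF-beta lists passed when adjusted over the list alone. In all, camera called 16 of the 17 lists at its preset correlation, and 0 held with an estimated correlation or by fry's directional test, whose adjusted p values were at least 0.362. With either of these, 0 lists had an unadjusted p under 0.05. Fry's mixed test, for changes in either direction, also called 0 lists; its unadjusted p values under 0.05 were those of the homeostatic list (adjusted p = 0.0812) and the type I interferon list (adjusted p = 0.262).

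**Figure D3:**
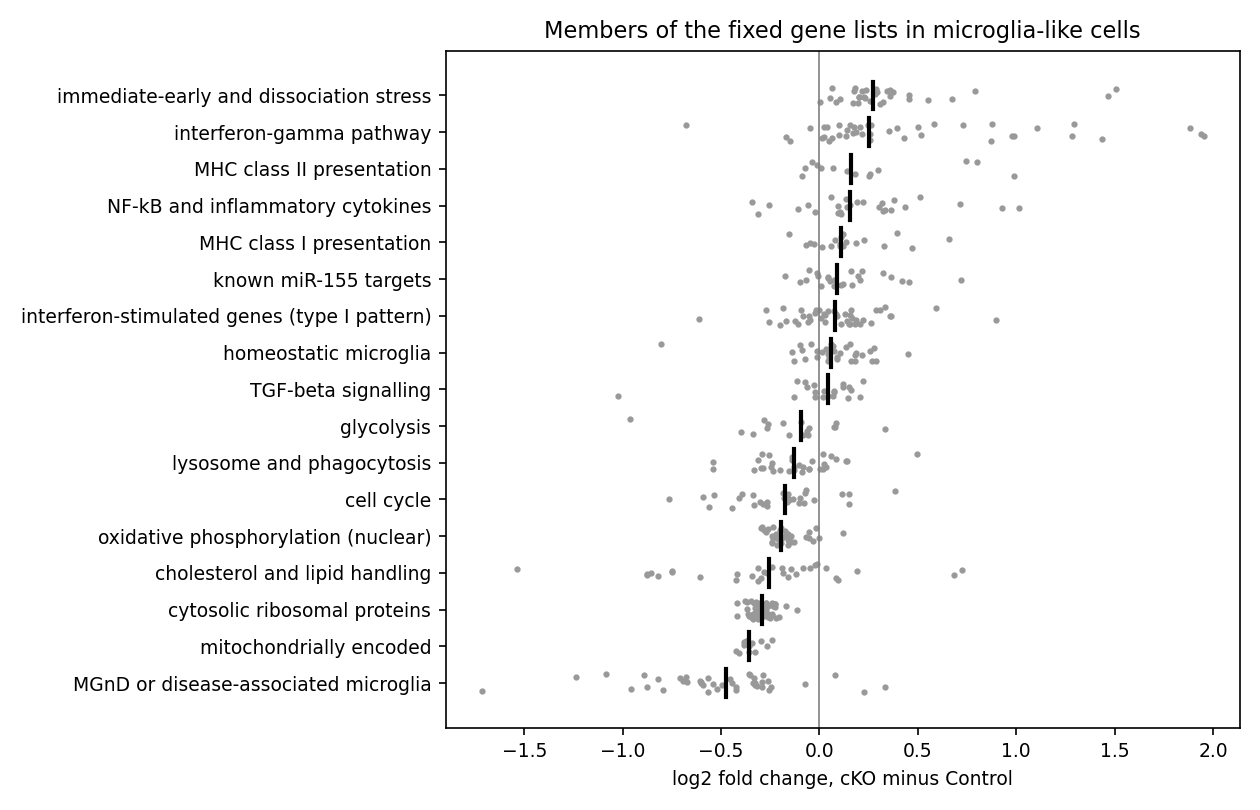
Log2 fold change (cKO minus Control) of each member (dots) of the 17 lists in microglia-like cells, with black bars at the list medians. The medians ran from -0.48 for the MGnD list to 0.27 for the stress list.

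Loss of a microRNA is usually read in the transcripts that carry its site. Known miR-155 targets had higher values in cKO in 19 of 25 genes (median 0.09), among them the tetraspanin gene Tspan14 (0.32), the transcription factor gene Cebpb (0.36) and Trp53inp1 (0.42). None passed when adjusted over the list alone; camera called the list (adjusted p = 5.46e-04), with adjusted p = 0.320 with an estimated correlation. Its median was 0.14 without cKO replicate 1 and 0.06 with MGnD-high cells left out. In MGnD-high cells, whose share was lower in cKO, 17 of 24 tested targets were lower and 3 higher than in other cells. The mix of states could therefore also move this list. A miR-155-5p seed site lay in the 3′ UTR of 17 of the 25 known targets. Across all 11609 tested genes with a 3′ UTR, the 1070 with a site had a median log2 change of 0.02 and the others 0.01. The difference of 0.0106 lay within the range of other heptamers, of which 82 of 419 gave at least as much (exact enumeration of these heptamers, two-sided p = 0.476). At an unadjusted p under 0.05, 47 genes with a site were higher and 44 lower. The 383 genes with the longer site had a difference of 0.0201 (exact p = 0.174 by the same enumeration), and with the replicate block the difference was 0.0113. It was 0.0244 without cKO replicate 1, 0.0189 without Control replicate 1, -0.00150 without Control replicate 2 and -0.00354 without cKO replicate 2.

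The MGnD-high cells of these mice differed broadly from the other microglia-like cells in the same libraries, with 3485 genes higher and 3400 lower of 12355 tested by edgeR with the library as a block. The 12 genes that define the state were left out. The largest rises were in Ch25h, the cholesterol 25-hydroxylase (log2 5.30), Baiap2l2 (4.58), the fatty-acid-binding protein gene Fabp3 (4.36), Lilrb4a (3.797) and H2-Aa (3.67). The largest falls were in Tmem204 (-1.73), Bank1 (-1.71), Tspan18 (-1.67), the lectin gene Clec4a2 (-1.65) and the interleukin-7 receptor gene Il7r (-1.64). Each of these 10 genes had the same direction in 4 of 4 libraries. All 30 remaining MGnD genes rose (median 1.68), as did 27 of 32 lysosome genes, 23 of 29 lipid genes, 36 of 44 type I interferon genes and all 62 ribosomal protein genes (median 1.07). Of 35 homeostatic genes 28 fell (median -0.45), and of 32 stress genes 23 fell (median -0.54). Of 24 known miR-155 targets 17 fell and 3 rose (median -0.22). The state was defined by 12 other members of the MGnD list, so the direction of that list here is not independent evidence.

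Whether genotype acted differently in MGnD-high and other cells was tested as an interaction. EdgeR called 0 of 12355 genes, with 561 at an unadjusted p under 0.05, and no other tool was run. The median interaction of the MGnD list was -0.02 and that of the cell cycle list -0.71, with 0 members past the threshold in either. Without 1 library the count was 38 (cKO replicate 1), 12 (Control replicate 1), 89 (Control replicate 2) and 52 (cKO replicate 2).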

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

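The tests without interferon-high cells, of the heptamers without CG and of state shares without cells carrying markers of another class were chosen after the data were seen; the others were fixed beforehand. Of 1031 gene values over the alternatives, 871 kept direction and side of the threshold, 140 newly passed, 9 no longer passed and 11 reversed. Of 255 list tests by camera at the preset correlation, 231 kept both, 20 lost the call and 4 turned in test direction. Medians crossed 0 for the type I interferon list without cKO replicate 2 (-0.0075) and without Control replicate 1 (-0.0012), and for MHC class II without Control replicate 1 (-0.016), besides those below. For the genotype comparison in microglia-like cells edgeR called 4 genes, and DESeq2 called 25; without a low-count filter there were 344, with thinned cells 17, without cells carrying markers of another class 2, and without interferon-high cells 0 (908 at an unadjusted p under 0.05). Leaving out 1 library gave from 8 genes (without cKO replicate 2) to 331 (without cKO replicate 1), where the lone sample was assumed to vary like the other group; the cause was not tested. The replicate block gave 6 genes and left the called lists at the preset correlation as they were. Of the 16 lists that camera called, 0 held with an estimated correlation and 0 by fry's directional test. The estimated correlations of these 16 lists ran from 0.0884 (known miR-155 targets) to 0.926 (mitochondrially encoded), all above the preset 0.01. The MGnD list had 0.638 and the ribosomal list 0.779. The fit has 2 residual degrees of freedom. Beyond these values the cause was not tested. The microglia-like difference was -0.180 points and the unnamed difference 0.255 points in cells of at least 2000 UMIs, a limit that leaves few unnamed cells. Interferon-high cells differed by 0.600 points with 1 gene more and -3.06 with 1 gene fewer, and cycling cells by 0.134 points when thinned to 1000 UMIs. Without 1 library the ranges were -0.108 to 0.442 points for BAM-like, -0.294 to 0.125 for monocyte-like, -2.07 to 0.141 for interferon-high and -0.612 to 0.0777 for cycling cells. The MGnD-high share was lower in cKO under every alternative run, by -14.3 to -4.90 points without 1 library. MHC-II-high droplets were more frequent in cKO under all of them, by 1.67 points without cells carrying markers of another class. The seed-site difference ran from -0.00354 to 0.0244, and with heptamers without CG only the exact p = 0.428. The interaction gave 12 to 89 genes without 1 library.

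Leaving out MGnD-high cells turned the median of the cell cycle list to 0.23 and the test direction of the homeostatic list at 0.00112, and the log2 values of Cybb (0.025), Axl (0.16), Ndufa1 (0.032), Stmn1 (0.041), Birc5 (0.041), Apoe (0.16) and P2ry12 (-0.018). Leaving out interferon-high cells turned the type I interferon median (-0.16), Ifit1 (-0.070) and Mx1 (-0.22). Without 1 library the log2 range was -0.0079 to 0.19 for P2ry12, -0.0331 to 12.1 for Xist, which Control replicate 1 lacks, and 0.0097 to 0.097 for the TGF-beta median, whose test direction turned. MGnD-high and interferon-high cells were picked by detection of genes that include Axl and Ifit1. Their removal shifts such genes by construction and tests no cause. Apart from Xist, the causes of the turned values were not tested. The BAM-like class had no value with no doublets removed, because its cells then lay in an unnamed cluster. Genotype in the other cell classes was not run, since none had 30 cells in every library. With 2 libraries per group no share could reach an exact p under 0.333, and Mir155hg rests on 19 UMIs.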

Other observations

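All hypotheses below arose from patterns seen in these data. The tests of the run code and of Y-linked genes were chosen after their results were seen, as was the heat-shock comparison at equal shares of cells with and without these UMIs. The decisions on the heat-shock and Esr1 tests were made stricter after their values were seen.

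Beyond the fixed states, microglia-like clusters differed in their leading genes. One cluster of 1125 cells was led by Tnf, Ccl4 and Cd83, with a median of 11620 UMIs per cell. Another, of 1078 cells, was led by the interferon-induced genes Cxcl10, Ifit3, Ifit2 and Isg15, and Iigp1 was among its first 5 genes. A cluster of 264 cells was led by the cell cycle genes Top2a and Mki67. Of 1137 cells in a cluster led by Ccr1, Klf4 and Fosb besides predicted genes, 902 came from Control replicate 1. A cluster of 2283 cells was led by Tsix, Hspa1b and Hspa1a, with Xist among its first 10 genes, and 169 of its cells came from Control replicate 1. Of the unnamed cells, 45 were led by H2-Aa, Cxcl9 and Cd74, with 10 and 20 from cKO replicates 1 and 2, and 6 and 9 from Control replicates 1 and 2. A further 22 cells were led by Ttr, Enpp2 and Mt3, of which 15 came from Control replicate 1. Cluster sizes were not compared between groups, because Xist and heat-shock genes were among the leading genes of a cluster.

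The lower MGnD-high share in cKO came with higher levels of heat-shock transcripts, which could reflect handling. Among cells without a UMI of Hspa1a, Hspa1b or Dnajb1, 88.9% of the gap between the groups was kept (8.56 of 9.62 points; 80.7% to 96.9% without 1 library), which met the bound of 75% set beforehand, but such cells have higher MGnD-high shares, so that points overstate what was kept. The ratio of cKO to Control was 0.659 over all cells and 0.761 in these, and among cells with such UMIs the groups overlapped, at 12.4% and 7.85% in cKO replicates 1 and 2 and 13.6% and 11.6% in Control replicates 1 and 2. With equal shares of both kinds of cells 62.1% of the gap was kept (51.6% to 68.2% without 1 library), between the bounds of 50% and 75%, so that handling and genotype cannot be told apart here. The run code and an effect of genotype also stay open, since the only cKO library of the shared code had 23.3% MGnD-high cells, below the 28.4% and 28.0% of its Control libraries, and cKO replicate 2, with 13.9%, is alone in its code.

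Control replicate 1 had 14 UMIs of Xist and 9 of Tsix in microglia-like cells, although it was labelled female. A male animal is argued against by its 2 UMIs from 4 Y-linked genes. A general loss of long nuclear RNAs is argued against by their median log2 ratio to the other libraries of -0.019, with Malat1 at -0.08, Neat1 at -0.23 and Kcnq1ot1 at 0.09 (Meg3 had at most 1 UMI per library). A single X chromosome may be the explanation, because 7 of 7 genes that escape X inactivation were lower, with a median of -0.37, below all of 10000 random sets of other X genes, while 153 other X genes had a median of 0.04. This hypothesis was found on the same data, no biological difference between the groups was tested for it, and whether it alters the other comparisons stays open.

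Cx3cr1 was lower and Esr1 higher in cKO, which could come from a CreERT2 allele at Cx3cr1 whose estrogen receptor sequence is counted as Esr1; the labels name no Cre driver. The excess of Esr1 had a ratio of 0.597 between MGnD-high and other cells (95% counting interval 0.400 to 0.825), and Cx3cr1 had 0.540, which met the criterion set beforehand. The Esr1 of the Control libraries had a like ratio of 0.547, so this allele and a rise of Esr1 itself cannot be told apart by it. Cx3cr1 in cKO was 0.559 of Control in MGnD-high cells and 0.543 in the others. Strain variants carried beside the locus also cannot be told apart, since 11.02% of 118 genes within 10 Mb had an unadjusted p under 0.05 (13.9% of 122 with Cx3cr1, Crtap, Glb1 and a predicted gene, left out because their values had been seen), above the 7.29% median of 922 windows of the same width, and higher than 89.8% of them, where the criterion set beforehand was 95%.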
